A study of Mus musculus with 16 samples.

How the data were processed

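Hippocampal RNA of female mice was measured on 16 Affymetrix GeneChip Mouse Gene 1.0 ST arrays, which read each gene with probes spread over the whole transcript. Per the labels, the mice were 3 months old, came from a mixed F2 background of C57BL/6J and DBA, and were either heterozygous for a deficiency of Crebbp (cbp+/-) or wild-type littermates. They lived in standard cages or in a large box with toys, tubing and running wheels. Enrichment lasted 2 weeks, and tissue was taken many hours after the box had last been rearranged, per the labels' protocols. Per the labels' protocols, RNA was extracted from each hippocampus on its own and equal amounts from 4 animals were pooled for each array, so that the 16 arrays stand for 64 animals, and the pools of a group are independent biological replicates. Groups and replicate numbers were taken from the titles: 5 arrays per genotype in standard cages and 3 per genotype in enrichment. Arrays are named here by genotype (WT or CBP), housing (SC for standard cage, EE for enrichment) and replicate number, as in CBP_EE_3.

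The deposited values are intensities on a linear scale, 1 per probe set and array, from 22.12 to 16520.86 with 0 missing. RMA is named for them per the submitters' processing notes, and GeneSpring GX is named for processing, normalization and statistics per the labels' protocols. The version of either, the statistical test and any baseline transformation are not given in the sources used here. The linear scale was read from the values themselves. Whether the values were centred on a baseline before the log was undone stays unknown, and scanner files were not used here. For single-colour intensities a direction between channels does not arise. The medians of the arrays over all deposited probe sets were 77.35, 77.95, 79.12, 78.71 and 79.03 for WT_SC_1 to WT_SC_5, and 85.46, 82.14 and 79.72 for WT_EE_1 to WT_EE_3. They were 79.28, 80.19, 76.7, 78.79 and 78.06 for CBP_SC_1 to CBP_SC_5, and 81.34, 82.43 and 77.65 for CBP_EE_1 to CBP_EE_3. The number of arrays limits the precision of every comparison. RMA carries no detection call, so dim probe sets were kept and left out only as an alternative.

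Of 28815 deposited probe sets, 23385 were in the platform's probe table. Of these, 21780 had exactly 1 gene symbol and were tested (19935 genes), and 1605 had several symbols and were not named. The other 5430 were unnamed here. By gene number, 21689 of those tested matched the RefSeq table of assembly GRCm38.p6 and 91 did not; 0 symbols needed an update. Because the array's own genome build is not given in the sources used here, that table served only for names, for which genes neighbour each other and for distances from Crebbp, and no coordinates are given. Genes of the Y chromosome are not named.

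Log2 of the deposited intensity was taken and analysed in R 4.3.3 with limma 3.58.1. lmFit fitted the mean of each of the 4 groups to all 16 arrays together (12 residual degrees of freedom), and eBayes moderated the variances. From this fit came 7 comparisons: enrichment against standard cage in each genotype, cbp+/- against wild type in each housing, the interaction (the difference between both housing effects), and the housing and genotype effects averaged with equal weight. P values were adjusted by Benjamini-Hochberg over all 21780 probe sets, with a threshold of 0.05. Changes are differences of log2 means with the standard error (SE) of the moderated fit, while group levels are given with their SD over arrays.

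Gene lists were fixed from textbook knowledge and not chosen on these samples: 31 lists, with 609 entries of which 566 matched, and 8 to 34 members each. They cover acetylation enzymes, activity-regulated immediate early genes, CREB-target neuropeptides and secreted factors, neurotrophins and growth factors, and the cell types and layers of the hippocampus. The latter are immature granule neurons, neural stem cells, proliferating cells, dentate granule cells, CA1 and CA3/CA2 pyramidal cells, excitatory synapses, GABAergic interneurons, oligodendrocytes, their progenitors, astrocytes, microglia and endothelial cells. Neighbouring sources of RNA (choroid plexus, meninges, ependyma, blood, thalamus, striatum and cortex) and glucocorticoid-responsive, circadian, chaperone, interferon, protocadherin beta, oxidative phosphorylation and ribosomal protein genes make up the rest. Some lists share genes, such as Bdnf, Per1 and Penk. Each list was tested with limma's camera with a preset inter-gene correlation of 0.01, using the brightest probe set of each gene and adjusting over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, and the number of members past the threshold adjusted over the list alone. A list's level on an array is the median over its members of the deviation from each gene's mean over all arrays.

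Genes were named by a rule. It took up to 10 per direction past the threshold or, where none passed, the 5 with the smallest p, named as not passing. It added 4 members of each list that passed, Crebbp and Ep300 in the genotype comparisons, and Bdnf, Dcx, Fos, Arc, Egr1, Vgf, Igf1, Npas4 and Ttr in the housing comparisons. Unnamed gene models could be skipped, and 1 gene that the rule took for cbp+/- housing is not reported here. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined.

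The alternatives set beforehand were quantile normalization, centring each array on its median, leaving out probe sets with a mean below the 40th percentile, testing all deposited probe sets, eBayes with trend and robust, no moderation, array weights, fitting only the groups compared, replicates 1 to 3 only, the replicate number as a block, and leaving out each array in turn. Hierarchical clustering of the 500 brightest probe sets then showed 4 sets of arrays that cross the study's groups. Set 1 holds replicates 1 and 2 of every group (8 arrays), set 2 replicate 3 and set 3 replicate 4 of both standard-cage groups, and set 4 replicate 5 of both standard-cage groups with replicate 3 of both enrichment groups. Their origin is not given in the sources used here. Alternatives with these sets as a block, with or without quantile normalization, with set 1 only, and with same-numbered wild-type and cbp+/- arrays of one housing as pairs were therefore chosen after seeing the data.

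Same-numbered WT and CBP arrays of a housing were taken as pairs. Their deviations from group means correlated at 0.544 to 0.767 in standard cages and 0.257 to 0.629 in enrichment. The own number was the best partner in 4 of 5 and 2 of 3 cases. Pair counts and sign-flip p values rest on this data-derived pairing. Across housings, correlations were -0.394 to -0.0124 in wild type and -0.0435 to 0.365 in cbp+/-. No array duplicated another (correlations of log2 values 0.966 to 0.998).

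The fit was tested on simulated data with the spread and group sizes measured here. For the housing effect in wild type over 21780 simulated probe sets, it recovered 10.4% of changes of 0.25 log2, 65.7% of changes of 0.5 and 90.9% of changes of 1 with independent noise. With array-set shifts as measured it recovered 25.4%, 59.7% and 92.4%, and 31.3%, 74.6% and 100% with the sets as a block. For the genotype effect in standard cages, it recovered 31.3%, 68.7% and 92.4% with independent noise, 22.4%, 67.2% and 98.5% with the shifts, and 46.3%, 91.0% and 98.5% with the shifts and the block.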

Results

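Hippocampal gene expression was measured in 16 pools of female mice that differed in Crebbp genotype and in housing. Crebbp encodes CBP, a histone acetyltransferase and coactivator of CREB. Each pool held RNA of 4 mice and was read on 1 array. There were 5 pools per genotype from standard cages and 3 per genotype after 2 weeks of enrichment, a large box with wheels and toys. The design asks which genes respond to enrichment, which depend on Crebbp, and whether the response differs between genotypes.

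The arrays differed from one another along lines that cross the study's groups. The first principal component held 34.1% of the variance. Of it, 91.1% lay between the 4 array sets, 6.42% between housings and 0.139% between genotypes. Housing held 24.9% of component 2 and 21.4% of component 3. The sets were clustered from these arrays, so their share is partly built in. So is the median correlation of log2 values, 0.996 within sets and 0.986 between. The range of signals also differed: the interquartile range on the log2 scale was 2.22 to 2.37 on the 3 wild-type enrichment arrays and 2.49 to 2.58 on the 5 wild-type standard-cage arrays. Values with the array sets as a block are therefore given beside the housing results. Sets 2 and 3 hold no enrichment arrays, so these rest on set 1 and 1 array per group in set 4. The sets were clustered from the same values that are tested, so the block lowers the residual spread partly by construction. Its p values may therefore be too small. The sets are balanced over genotypes, so the block leaves the genotype estimates as they are and changes only their errors.

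Crebbp itself was not lower on the arrays labelled cbp+/-. Its log2 signal in standard cages was 9.57 ± 0.22 on the arrays labelled cbp+/- and 9.43 ± 0.18 on wild-type arrays (SD, n = 5 each), a difference of 0.14 (SE 0.099, adjusted p = 1.00) that was positive in 5 of 5 same-numbered pairs. In enrichment it was 9.36 ± 0.025 against 9.26 ± 0.082 (n = 3 each), a difference of 0.098 (SE 0.13, adjusted p = 0.976), higher in 3 of 3 pairs. Averaged over housings the difference was 0.12 (SE 0.081, adjusted p = 1.00), higher in 8 of 8 pairs. The probes of this design lie along the whole transcript, so a mutant transcript that is still made would be read too and the check of the labels is partial. Ep300, which encodes the paralogous acetyltransferase p300, differed between genotypes by 0.049 (SE 0.13) in standard cages, -0.023 (SE 0.16) in enrichment and 0.013 (SE 0.10) on average, with 4 of 5, 1 of 3 and 5 of 8 pairs higher (adjusted p = 1.00 in each).

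**Figure D1:**
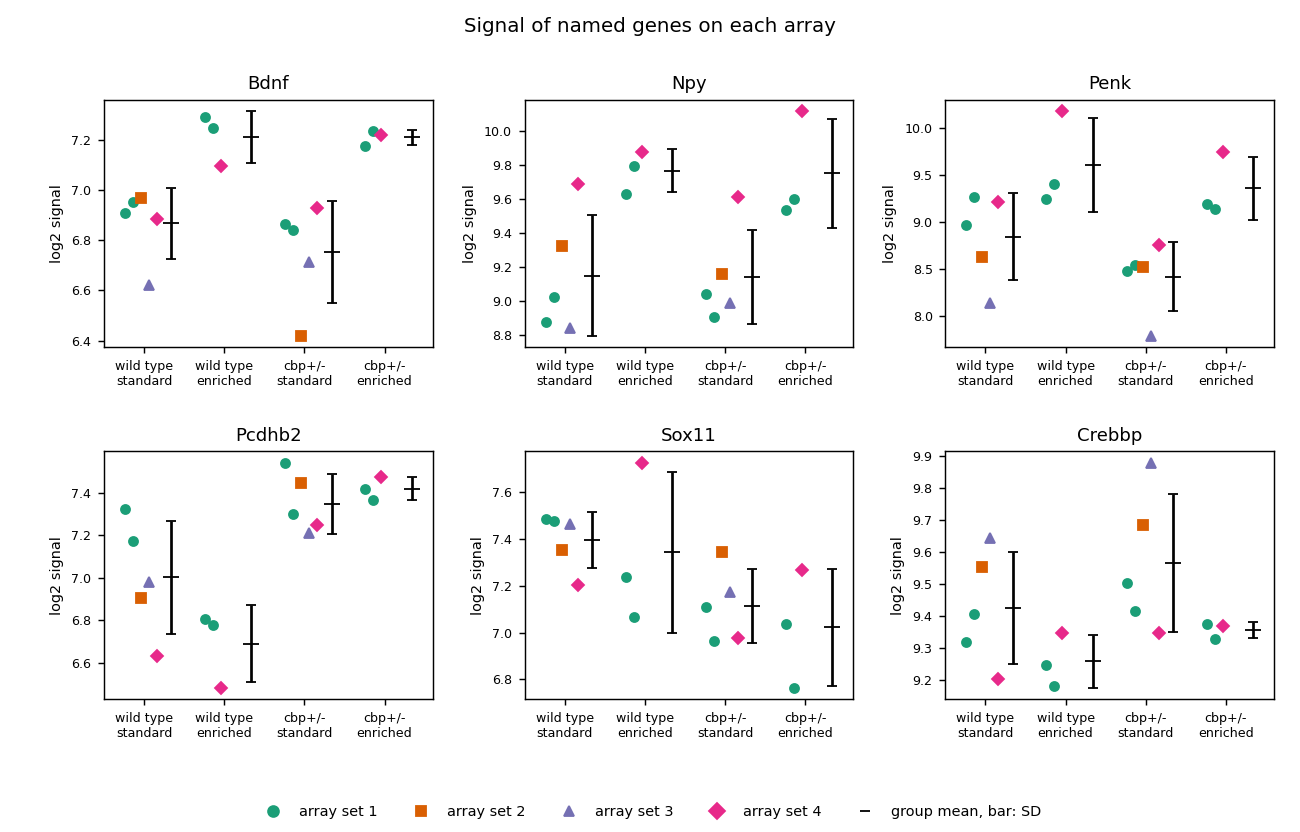
Log2 signal (vertical axis) of Bdnf, Npy, Penk, Pcdhb2, Sox11 and Crebbp on each array of the 4 groups (horizontal axis), with markers coloured and shaped by array set, a horizontal bar at the group mean and an error bar of 1 SD (n = 5 per standard-cage group, n = 3 per enrichment group). Bdnf averages 7.21 in both enrichment groups against 6.87 and 6.75 in standard cages.

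In wild-type mice, enrichment went with lower levels of excitatory synapse genes and with higher Bdnf, which did not pass the threshold alone. Of 25 excitatory synapse and glutamate receptor genes, 24 were lower, with a median change of -0.24 log2 (-0.15 with quantile normalization, -0.080 with quantile normalization and the array sets as a block), and the list did not pass with an estimated correlation (adjusted p = 0.481). Bdnf, a neurotrophin that CREB activates, had a log2 signal of 7.21 ± 0.10 in enrichment (SD, n = 3) and 6.87 ± 0.14 in standard cages (n = 5), a difference of 0.34 (SE 0.10, adjusted p = 0.153) with 3 of 3 enrichment arrays above every standard-cage array. Fos, an immediate early transcription factor, differed by 0.50 (SE 0.18, adjusted p = 0.189, 2 of 3 arrays above every standard-cage array) and by 0.30 without WT_EE_1, but by 0.96 in array set 1 and -0.27 in set 4. Gene models without a name apart, the genes with the smallest p were dim: Tnnc1 (troponin C of slow muscle, 0.37, SE 0.053), Trim80 (0.26, SE 0.039), Gstp3 (a glutathione transferase, 0.35, SE 0.055), Cyp2d10 (a cytochrome P450, 0.42, SE 0.068) and Myog (myogenin, a muscle transcription factor, 0.35, SE 0.057). Each had an adjusted p of 0.0517 and 3 of 3 arrays above every standard-cage array.

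No probe set of 21780 passed an adjusted p of 0.05 with limma in this comparison (count 0), and 3884 had an unadjusted p under 0.05. Some settings called more, from 15 with the array sets as a block to 6513 within array set 1. Without CBP_SC_3, CBP_EE_2 or CBP_EE_3 the count was 3, 7 and 19. The median change followed brightness. It was 0.037 to 0.130 in the dimmest 5 of 10 brightness classes and -0.015 to -0.093 in the brightest 5. Of the 100 probe sets with the smallest p, 86 were both in the dimmer part of the array and higher in enrichment.

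**Figure D2:**
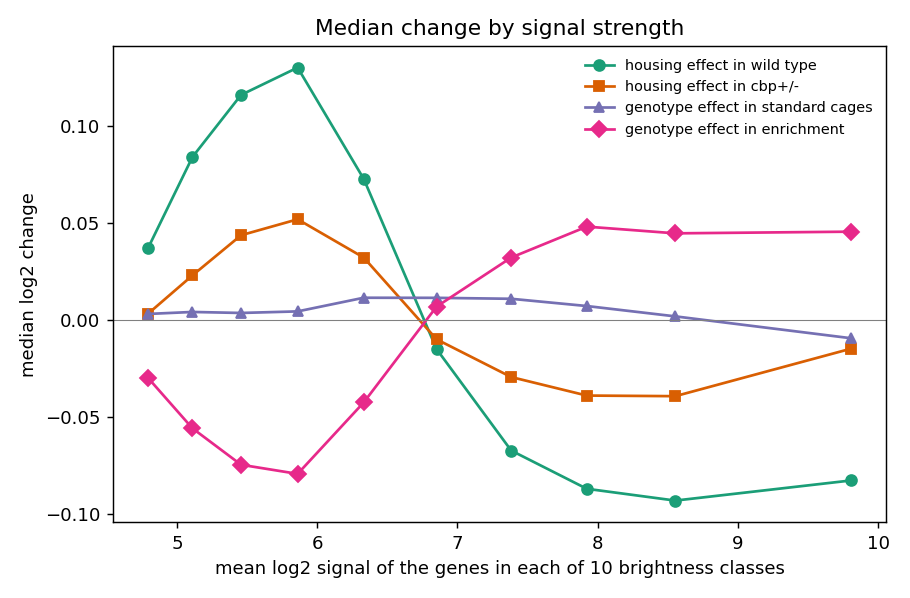
Median log2 change (vertical axis) against the mean log2 signal (horizontal axis) of the probe sets in each of 10 brightness classes, with 1 line for each of the housing effects in wild type and in cbp+/- and the genotype effects in standard cages and in enrichment. In the housing effect of wild type, the fourth class lies at 0.130 and the ninth at -0.093, while in cbp+/- these classes lie at 0.052 and -0.039.

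Of the gene lists, 7 were lower in wild-type enrichment and 0 higher, a balance that depends on the setting. Quantile normalization gave 3 higher and 2 lower, leaving out dim probe sets 4 and 1, array set 1 only 2 and 3, and the set block 1 and 3. Immediate early and CREB-target genes passed as higher with quantile normalization (adjusted p = 0.000378 and 0.00614) and without dim probe sets (0.000213 and 0.000165). The excitatory synapse list (adjusted p = 1.2e-07, 3 of 3 enrichment arrays below the standard-cage mean) included Grin2b, an NMDA receptor subunit (-0.25, SE 0.091, adjusted p = 0.198), Camk2b, a calcium-dependent kinase of the synapse (-0.38, SE 0.15), the scaffold gene Dlgap1 (-0.35, SE 0.14) and the kainate receptor Grik2 (-0.29, SE 0.12). Without WT_EE_3, Grin2b was at -0.14 and Dlgap1 at -0.16. With the array sets as a block the list's median was -0.14 (adjusted p = 1.0e-07), with within-set medians of -0.15 in set 1 and -0.14 in set 4. The 22 clustered protocadherin beta genes, which encode adhesion proteins, had a median of -0.12 with 17 lower (adjusted p = 0.00373, adjusted p = 0.616 with an estimated correlation, 3 of 3 arrays). Pcdhb18 differed by -0.32 (SE 0.11, adjusted p = 0.180) and Pcdhb10 by -0.26 (SE 0.11), or -0.17 without WT_SC_1. With the array sets as a block their median was -0.27 (adjusted p = 1.6e-09), and within sets it was -0.41 in set 1 and -0.12 in set 4. Their call ended without WT_SC_1 (adjusted p = 0.0844).

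The list of 24 acetylation enzymes, CBP and p300 among them, had a median of -0.12 with 18 lower (adjusted p = 0.00373, adjusted p = 0.481 with an estimated correlation, 3 of 3 arrays). Kat5 (-0.21, SE 0.079, adjusted p = 0.205) and Kat2a (-0.24, SE 0.13), both lysine acetyltransferases, were below every standard-cage array on 3 of 3 arrays. The 16 circadian genes had a median of -0.17 with 13 lower (adjusted p = 0.00373, adjusted p = 0.616 with an estimated correlation, 3 of 3 arrays), among them Bhlhe41 (-0.48, SE 0.19) and Tef (-0.22, SE 0.095), and their call ended without WT_EE_3 (adjusted p = 0.105), where these genes were at -0.24 and -0.14. The 21 oligodendrocyte genes had a median of -0.098 with 17 lower (adjusted p = 0.00373, adjusted p = 0.616 with an estimated correlation, 2 of 3 arrays), among them Cnp (-0.46, SE 0.18) and Mag (-0.40, SE 0.20), which encode myelin proteins. Without WT_EE_3 these were at -0.23 and -0.20, and in array sets 1 and 4 Cnp was at -0.011 and -0.83 and Mag at 0.13 and -0.69. Without WT_SC_3 or WT_EE_3 that call ended (adjusted p = 0.0603 and 0.154).

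The 19 glucocorticoid-responsive genes had a median of -0.13 with 15 lower (adjusted p = 0.0369, adjusted p = 0.616 with an estimated correlation, 3 of 3 arrays), with Fkbp5, a chaperone of the glucocorticoid receptor, at -0.27 (SE 0.14). Their call ended without WT_SC_3 (adjusted p = 0.135), WT_SC_5 (0.133) or WT_EE_3 (0.244). The 16 astrocyte genes had a median of -0.10 with 13 lower (adjusted p = 0.0381, adjusted p = 0.616 with an estimated correlation), with Clu, a secreted chaperone, at -0.16 (SE 0.092), but the list level was lower on only 1 of 3 enrichment arrays. Leaving out WT_SC_1, WT_SC_2, WT_SC_3 or WT_EE_3 ended that call (adjusted p = 0.0838, 0.0561, 0.0603 and 0.733). With the array sets as a block, the acetylation (-0.042, adjusted p = 0.0640), circadian (-0.091, adjusted p = 0.0640), oligodendrocyte (-0.067, adjusted p = 0.0978), glucocorticoid (-0.048, adjusted p = 0.215) and astrocyte lists (-0.061, adjusted p = 0.0640) no longer passed. Medians of the acetylation, oligodendrocyte, glucocorticoid and astrocyte lists turned positive under some settings, given below. With quantile normalization, of these 7 lists the excitatory synapse (adjusted p = 0.00174) and protocadherin lists (adjusted p = 0.000564) passed. Of the members of the 7 lists, 0 passed over all genes tested and 0 adjusted over the list alone.

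The immediate early genes as a list did not pass in wild type (median 0.098, 25 of 34 higher, adjusted p = 0.113, adjusted p = 0.707 with an estimated correlation), although 5 passed adjusted over the list alone against 0 over all genes tested. With the array sets as a block their median was 0.19 (adjusted p = 0.00169), and within sets it was 0.34 in set 1 and -0.10 in set 4. The CREB-target list had a median of 0.16 with 13 of 15 higher (adjusted p = 0.0818, adjusted p = 0.481 with an estimated correlation), passed with fry (adjusted p = 0.0368), and had 0 members past the threshold adjusted over the list alone. Within array sets 1 and 4 the median of the CREB-target list was 0.192 and 0.188. Among the genes fixed for housing, Arc differed by 0.22 (SE 0.34; 0.99 in set 1 and -0.29 in set 4), Egr1 by 0.28 (SE 0.30), Npas4 by 0.15 (SE 0.18; 0.45 and -0.18), the secreted peptide precursor Vgf by 0.15 (SE 0.12) and the growth factor Igf1 by 0.069 (SE 0.059). Dcx, a marker of newborn neurons, differed by -0.036 (SE 0.10), and Ttr, the transthyretin gene of the choroid plexus, by 0.15 (SE 1.10).

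In cbp+/- mice, enrichment went with higher CREB-target neuropeptides and immediate early genes and with lower excitatory synapse genes. Of these 3 lists only the CREB-target list passed with an estimated correlation (adjusted p = 0.0149, against 0.610 for immediate early and 0.509 for excitatory synapse genes). Penk, the proenkephalin gene, had a log2 signal of 9.36 ± 0.33 in enrichment (SD, n = 3) and 8.41 ± 0.37 in standard cages (n = 5), a 1.92-fold difference (log2 0.94, SE 0.28, 3 of 3 arrays above every standard-cage array). Npy, which encodes neuropeptide Y, was at 9.75 ± 0.32 against 9.14 ± 0.28, a 1.52-fold difference (log2 0.61, SE 0.20, 1 of 3 arrays above every standard-cage array). Bdnf was at 7.21 ± 0.029 against 6.75 ± 0.20, a 1.37-fold difference (log2 0.46, SE 0.10, 3 of 3 arrays). Of the 15 CREB-target genes 13 were higher, with a median of 0.19 log2 (adjusted p = 1.3e-05, 3 of 3 arrays above the standard-cage mean). This was the only list call of any comparison to hold with an estimated correlation, and it passed with fry too (adjusted p = 0.0133). With the array sets as a block its median was 0.17 (adjusted p = 1.2e-06, adjusted p = 0.00958 with an estimated correlation), with 0.16 within set 1 and 0.13 within set 4. The list of striatal genes, a neighbouring tissue, shares Penk and moved the same way. It had a median of 0.053 with 11 of 13 higher (adjusted p = 0.0572), 0.086 with the set block (adjusted p = 0.0228, adjusted p = 0.227 with an estimated correlation), and 0.13 and 0.10 within sets 1 and 4.

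Tested gene by gene, 0 of 21780 probe sets passed with limma, 615 had an unadjusted p under 0.05, and array weights called 1039. Genes with some of the smallest p were Bdnf, Dcc (a netrin receptor, -0.38, SE 0.093) and Anapc1 (a subunit of the anaphase-promoting complex, -0.24, SE 0.060). All had an adjusted p of 0.999 and 3 of 3 enrichment arrays beyond every standard-cage array. In the CREB-target list 3 genes (Npy, Penk and Bdnf) passed adjusted over the list alone, and 0 passed over all genes tested. The list's other named member, Vgf, differed by 0.30 (SE 0.12, 2 of 3 arrays).

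The immediate early list rose in cbp+/- enrichment, with 30 of 34 members higher, a median of 0.11 and 3 of 3 arrays above the standard-cage mean (adjusted p = 0.00151, adjusted p = 0.610 with an estimated correlation). With the array sets as a block the median was 0.16 (adjusted p = 5.2e-09), and within sets it was 0.19 in set 1 and 0.067 in set 4. Inhba, an activin subunit, differed by 0.23 (SE 0.089) and Maff, a small Maf transcription factor, by 0.12 (SE 0.057), both with 3 of 3 arrays above every standard-cage array. Nr4a3, an orphan nuclear receptor, differed by 0.16 (SE 0.074, 1 of 3). Adjusted over the list alone 1 gene passed, Bdnf. Of the genes fixed in advance, Fos differed by 0.33 (SE 0.18), Arc by 0.22 (SE 0.34), Egr1 by 0.052 (SE 0.30), Npas4 by 0.16 (SE 0.18), Igf1 by 0.053 (SE 0.059), Dcx by -0.14 (SE 0.10) and Ttr by -1.23 (SE 1.10), or -0.35 without CBP_SC_3. The 19 chaperone genes had a median of 0.085 with 16 higher (adjusted p = 0.00862, adjusted p = 0.451 with an estimated correlation, 3 of 3 arrays). They included Hspa1a (0.22, SE 0.092) and Hsph1 (0.25, SE 0.11), which encode inducible heat shock proteins. With the set block their median was 0.085 (adjusted p = 0.00571), with 0.052 in set 1 and 0.069 in set 4, and the call ended without CBP_SC_4 (adjusted p = 0.0971) or CBP_EE_3 (0.601).

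Lower in cbp+/- enrichment were 5 lists, against 3 higher, and this balance too depends on the setting: 2 lower and 5 higher with quantile normalization, 3 and 6 with dim probe sets left out, and 2 and 4 with the set block. Excitatory synapse genes had a median of -0.15 with 22 of 25 lower (adjusted p = 1.6e-05, adjusted p = 0.509 with an estimated correlation, 3 of 3 arrays), among them Syn2, a synaptic vesicle protein gene (-0.22, SE 0.11), and Grik2 (-0.22, SE 0.12). Their set-block median was -0.069 (adjusted p = 0.00105), with -0.092 in set 1 and 0.020 in set 4. Acetylation enzymes had a median of -0.087 with 20 of 24 lower (adjusted p = 0.00267, adjusted p = 0.451 with an estimated correlation, 3 of 3 arrays), among them Kat6a (-0.24, SE 0.11) and Ncoa3 (-0.22, SE 0.10), and the set block gave -0.045 (adjusted p = 0.0552). The dentate granule cell list had a median of -0.099 with 9 of 14 lower (adjusted p = 0.0249, adjusted p = 0.569 with an estimated correlation, 3 of 3 arrays), among them Npnt (-0.27, SE 0.14) and Dock10 (-0.14, SE 0.078). Its call ended without CBP_SC_4 (adjusted p = 0.126), CBP_EE_2 (0.0731) or CBP_EE_3 (0.0973), and the set block gave -0.042 (adjusted p = 0.276). Circadian genes had a median of -0.15 with 15 of 16 lower (adjusted p = 0.00355, adjusted p = 0.610 with an estimated correlation, 3 of 3 arrays), with Hlf, a PAR bZIP factor, at -0.16 (SE 0.089). The set block gave -0.033 (adjusted p = 0.276), and the call ended without CBP_SC_3 (adjusted p = 0.141). Choroid plexus genes had a median of -0.11 with 19 of 21 lower (adjusted p = 0.00166, adjusted p = 0.634 with an estimated correlation, 3 of 3 arrays), with Kl, the klotho gene, at -0.43 (SE 0.26), or -0.15 without CBP_SC_3. The set block gave -0.043 (adjusted p = 0.0922), and without CBP_SC_3 the call ended (median 0.029, adjusted p = 0.724). Apart from the genes named for the CREB-target and immediate early lists, 0 members of the 8 lists passed adjusted over the list alone, and 0 over all genes tested. Quantile normalization ended the calls of the acetylation (adjusted p = 0.0829), dentate granule (0.161) and circadian lists (0.0912).

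Averaged over both genotypes, enrichment went with higher CREB-target and immediate early lists and a lower excitatory synapse list. None of the 3 passed with an estimated correlation (adjusted p = 0.173, 0.624 and 0.384). CREB-target genes had a median of 0.16 with 14 of 15 higher (adjusted p = 0.00251, 6 of 6 enrichment arrays above the standard-cage mean of their genotype), and fry gave 0.00115. The set block gave a median of 0.095 (adjusted p = 0.000906). Penk differed by 0.85 (SE 0.20, adjusted p = 0.127, 5 of 6 arrays), Npy by 0.61 (SE 0.14, adjusted p = 0.127, 3 of 6), Bdnf by 0.40 (SE 0.074, adjusted p = 0.114, 6 of 6) and Adcyap1, which encodes the neuropeptide PACAP, by 0.16 (SE 0.058, 4 of 6), arrays counted where they lay above every standard-cage array of their genotype. With the set block Npy passed alone (0.57, adjusted p = 0.0358), and with quantile normalization as well Npy (0.62) and Penk (0.67) passed, each with adjusted p = 0.0351. Adjusted over the list alone, 3 CREB-target genes passed, and 6 with the set block.

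Immediate early genes had a median of 0.11 with 29 of 34 higher on average (adjusted p = 0.0189, adjusted p = 0.624 with an estimated correlation, 5 of 6 arrays). The set block gave 0.19 (adjusted p = 2.3e-06), and without WT_EE_1 (adjusted p = 0.105), WT_EE_2 (0.0934) or CBP_SC_1 (0.0555) the call ended. Adjusted over the list alone 7 genes passed, and 17 with the set block, against 0 over all genes tested. Maff (0.20, SE 0.040, adjusted p = 0.124, 6 of 6 arrays), Inhba (0.27, SE 0.063, adjusted p = 0.127, 6 of 6), Ptgs2, the inducible cyclooxygenase (0.34, SE 0.094, adjusted p = 0.142, 5 of 6), and Fos (0.41, SE 0.13, 4 of 6) were among these 7. Of the others fixed in advance, Arc differed by 0.22 (SE 0.24) and by 0.53 with the set block, Egr1 by 0.16 (SE 0.21) and by 0.44 with the set block, Npas4 by 0.15 (SE 0.13), Vgf by 0.23 (SE 0.085), Igf1 by 0.061 (SE 0.042), Dcx by -0.090 (SE 0.074) and Ttr by -0.54 (SE 0.78).

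All 25 excitatory synapse genes were lower on average (median -0.19, adjusted p = 2.5e-08, adjusted p = 0.384 with an estimated correlation, 6 of 6 arrays), among them Syn2 (-0.23, SE 0.075, adjusted p = 0.168) and Grik2 (-0.25, SE 0.082, adjusted p = 0.169). The set block gave -0.10 (adjusted p = 3.1e-07), and 0 members passed adjusted over the list alone against 8 with the block. Acetylation enzymes had a median of -0.11 with 20 of 24 lower (adjusted p = 0.000841, adjusted p = 0.384 with an estimated correlation, 6 of 6 arrays), with the coactivator Ncoa3 at -0.18 (SE 0.073). The set block gave -0.055 (adjusted p = 0.0301). Circadian genes had a median of -0.16 with 14 of 16 lower (adjusted p = 0.000841, adjusted p = 0.583 with an estimated correlation, 6 of 6 arrays), with the clock repressor Cry2 at -0.33 (SE 0.13), and the set block gave -0.039 (adjusted p = 0.105). Protocadherin beta genes had a median of -0.071 with 17 of 22 lower (adjusted p = 0.0123, adjusted p = 0.632 with an estimated correlation, 4 of 6 arrays), and the set block gave -0.21 (adjusted p = 1.7e-11) with 12 members past the threshold adjusted over the list alone against 0 without it. Pcdhb18 differed by -0.26 (SE 0.079, adjusted p = 0.161) and by -0.37 with the block (adjusted p = 0.0469), and the list's call ended without WT_SC_1 (adjusted p = 0.106) or CBP_SC_1 (0.0573). Oligodendrocyte genes had a median of -0.076 with 17 of 21 lower (adjusted p = 0.0411, adjusted p = 0.632 with an estimated correlation, 4 of 6 arrays) but 0.0083 with the set block (adjusted p = 0.629) and 0.083 within array set 1. Leaving out any of WT_SC_3, WT_SC_4, WT_EE_1, WT_EE_3, CBP_SC_1, CBP_SC_3, CBP_SC_5 or CBP_EE_2 ended that call (adjusted p = 0.0506 to 0.26). Quantile normalization ended the acetylation (adjusted p = 0.178), circadian (0.124) and oligodendrocyte (0.644) calls.

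Gene by gene, 0 probe sets passed for the averaged housing effect with limma and 4168 had an unadjusted p under 0.05. Gene models without a name apart, the smallest p belonged to Gstp3 (0.26, SE 0.039, adjusted p = 0.0791, 6 of 6 arrays above every standard-cage array), Trim80 (0.18, SE 0.028, 5 of 6), Cyp2d10 (0.30, SE 0.048, 6 of 6) and Tnnc1 (0.23, SE 0.037, 3 of 6), the last 3 with an adjusted p of 0.0880. Other settings called 5 (trend and robust), 11 (no moderation), 15 (set block), 9 (quantile normalization with the set block), 326 (replicate block), 5470 (array set 1 alone) and 6167 (array weights). Without CBP_EE_3 the count was 230, and without WT_EE_2 it was 1. With the set block Cyp2d10 passed (0.32, adjusted p = 0.0469).

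The housing effects of the genotypes correlated across genes at Pearson's r of 0.62 and Spearman's rank correlation of 0.59, and 72.2% of the probe sets had the same sign, although genes are not independent replicates. Within array set 1 alone Pearson's r was 0.62, and with the sets as a block 0.57. The effects share no array, but same-numbered arrays of both genotypes vary together. When the housing was moved over the 8 same-numbered pairs, 27 of 56 splits, the real one included, gave a Pearson's r at least as high as the real one (median of the others 0.60). Within array sets this held for 2 of 12, again with the real one (median of the others 0.53). The correlation over all arrays is therefore not evidence of a shared response to enrichment.

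In standard cages, immature granule neuron and oligodendrocyte lineage lists were slightly lower and protocadherin beta genes slightly higher on cbp+/- arrays. None of these lists passed with an estimated correlation (adjusted p = 0.0684 for immature granule neurons, 0.183 to 0.416 for the others). Sox11, a transcription factor of newborn neurons, had a log2 signal of 7.11 ± 0.16 on cbp+/- arrays and 7.40 ± 0.12 on wild-type arrays (SD, n = 5 each), a difference of -0.28 (SE 0.12, lower in 5 of 5 pairs). Pcdhb2 was at 7.35 ± 0.14 on cbp+/- arrays, 0.35 above wild type (SE 0.11, higher in 5 of 5 pairs). Of 24 immature granule neuron genes 16 were lower (median -0.045, adjusted p = 0.00295). The list level was lower in 5 of 5 pairs and the median of the members' differences in 4 of 5. Sox4 (-0.17, SE 0.12) and Dpysl3, a regulator of axon growth (-0.18, SE 0.085), were also lower in 5 of 5 pairs. Dcx was flat (mean signal 131 against 132 in wild type), so fewer newborn neurons are not shown.

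Gene by gene, 0 of 21780 probe sets passed with limma, 215 had an unadjusted p under 0.05, and 0 passed under every other setting run, array weights included. The smallest p belonged to Plau, the urokinase gene (-0.17, SE 0.040), Itih3 (0.24, SE 0.056), Mtmr10 (-0.18, SE 0.046), Bfsp2 (-0.17, SE 0.044) and Cdk5rap1 (0.21, SE 0.058), each with an adjusted p of 1.00 and the same direction in 5 of 5 pairs. In all, 12 lists passed, 9 lower and 3 higher, with 0 members of any past the threshold over all genes tested or adjusted over the list alone.

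Among glia, 10 of 11 oligodendrocyte progenitor genes were lower (median -0.083, adjusted p = 0.000369, adjusted p = 0.183 with an estimated correlation, 4 of 5 pairs), with Sox6 at -0.11 (SE 0.041) and Bcas1 at -0.23 (SE 0.11), or -0.12 without WT_SC_4. Of 21 oligodendrocyte genes 18 were lower (median -0.080, adjusted p = 0.000336, adjusted p = 0.416 with an estimated correlation, 3 of 5 pairs), with Opalin at -0.21 (SE 0.10) and Mbp, myelin basic protein, at -0.13 (SE 0.10). That call ended without WT_SC_3 (adjusted p = 0.141) or CBP_SC_4 (0.0627), with replicates 1 to 3 only (0.0931) and in array set 1 only (0.764). Its members' median differences in sets 1 to 4 were -0.010, -0.11, -0.40 (pair SC_4) and 0.0057. Of 16 astrocyte genes 13 were lower (median -0.040, adjusted p = 0.00686, adjusted p = 0.416 with an estimated correlation, 4 of 5 pairs), with Ppp1r3c, a glycogen-targeting subunit, at -0.22 (SE 0.094) and the filament gene Gfap at -0.17 (SE 0.13). Without WT_SC_1 (adjusted p = 0.0708) or CBP_SC_4 (0.0808) it ended.

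Among neurons, 10 of 14 dentate granule genes were lower (median -0.051, adjusted p = 0.0294, adjusted p = 0.416 with an estimated correlation, 4 of 5 pairs), with Tdo2, tryptophan dioxygenase, at -0.13 (SE 0.068) and the channel gene Trpc6 at -0.22 (SE 0.12), or -0.14 without CBP_SC_3. Leaving out WT_SC_1, WT_SC_4, CBP_SC_1, CBP_SC_2 or CBP_SC_5 ended that call (adjusted p = 0.0874 to 0.343), as did quantile normalization (adjusted p = 0.0508) and the replicate block (adjusted p = 0.0531). Of 14 CA3/CA2 genes 10 were lower (median -0.036, adjusted p = 0.0294, adjusted p = 0.182 with an estimated correlation, 3 of 5 pairs), with Socs2, a suppressor of cytokine signalling, at -0.17 (SE 0.076). That call ended without WT_SC_1, WT_SC_2, CBP_SC_1, CBP_SC_2 or CBP_SC_4 (adjusted p = 0.0681 to 0.181). It also ended with the array-set (0.0775), replicate (0.0627) and pair blocks (0.0862). Of 13 striatal genes 9 were lower (median -0.035, adjusted p = 0.00595, adjusted p = 0.0758 with an estimated correlation, 5 of 5 pairs), with the dopamine receptor Drd2 at -0.15 (SE 0.051) and Penk at -0.43 (SE 0.25), or -0.27 without CBP_SC_4. Of 15 cortical genes 12 were lower (median -0.033, adjusted p = 0.0261, adjusted p = 0.187 with an estimated correlation, 4 of 5 pairs), with Cdh13 at -0.14 (SE 0.062) and Etv1 at -0.27 (SE 0.13). Without WT_SC_3, CBP_SC_1, CBP_SC_4 or CBP_SC_5 that call ended (adjusted p = 0.0547 to 0.235). Of 16 circadian genes 13 were lower (median -0.040, adjusted p = 0.0294, adjusted p = 0.534 with an estimated correlation, 4 of 5 pairs), with Hlf at -0.17 (SE 0.077). Leaving out WT_SC_1, WT_SC_3, WT_SC_4, CBP_SC_1, CBP_SC_2 or CBP_SC_5 ended it (adjusted p = 0.0708 to 0.413), as did quantile normalization (adjusted p = 0.0536).

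Higher on cbp+/- arrays in standard cages were 19 of 22 protocadherin beta genes (median 0.12, adjusted p = 9.0e-07, adjusted p = 0.416 with an estimated correlation, 4 of 5 pairs), with Pcdhb7 at 0.37 (SE 0.20), and their call ended without WT_SC_3 (adjusted p = 0.0599). Of 21 choroid plexus genes 19 were higher (median 0.12, adjusted p = 8.0e-05, adjusted p = 0.467 with an estimated correlation) but the list was higher in only 2 of 5 pairs, with Kl at 0.32 (SE 0.23). Without CBP_SC_3 Kl was at 0.045 and the call ended (median -0.014, adjusted p = 0.159). The median difference of its members was 0.0024 in array set 1 and 0.59 in set 2, which holds CBP_SC_3. Of 12 ependymal genes 10 were higher (median 0.083, adjusted p = 0.00751, adjusted p = 0.354 with an estimated correlation, 4 of 5 pairs), with Ak7, an adenylate kinase of cilia, at 0.16 (SE 0.089). Without WT_SC_2 (adjusted p = 0.144), WT_SC_3 (0.0656), CBP_SC_3 (0.102) or CBP_SC_5 (0.194) that call ended.

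In enrichment, protocadherin beta genes were again higher on cbp+/- arrays, though the list did not pass with an estimated correlation (adjusted p = 0.775). Pcdhb2 had a log2 signal of 7.42 ± 0.052 on cbp+/- arrays and 6.69 ± 0.18 on wild-type arrays (SD, n = 3 each), a 1.66-fold difference (log2 0.73, SE 0.15, adjusted p = 0.924, 3 of 3 pairs). Pcdhb6 differed by 0.45 (SE 0.12), Pcdhb10 by 0.42 (SE 0.12) and Pcdhb4 by 0.33 (SE 0.15), or 0.22 without WT_EE_3. Of the 22 members 20 were higher (median 0.19, adjusted p = 6.9e-09, 3 of 3 pairs), and 3 passed adjusted over the list alone (Pcdhb2, Pcdhb10 and Pcdhb6) against 0 over all genes tested. Leaving out any 1 array did not end this call.

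The other 4 lists that passed in enrichment were higher on cbp+/- arrays too, with 0 members past the threshold over all genes tested or adjusted over the list alone, and quantile normalization ended the call of each (adjusted p = 0.107 to 0.172). It left protocadherins as the 1 list higher, with 3 lower: dentate granule (adjusted p = 0.00774), oligodendrocyte progenitor (0.0468) and cortical genes (0.0384). With the set block added 3 were higher and 5 lower. Oxidative phosphorylation genes had a median of 0.14 with 24 of 28 higher (adjusted p = 0.000784, adjusted p = 0.814 with an estimated correlation, 2 of 3 pairs), with Atp5b, an ATP synthase subunit, at 0.21 (SE 0.13, 0.14 without WT_EE_3) and Sdha, of succinate dehydrogenase, at 0.20 (SE 0.12). Without WT_EE_1 (adjusted p = 0.206) or CBP_EE_3 (0.555) the call ended. Chaperones had a median of 0.092 with 17 of 19 higher (adjusted p = 0.00562, adjusted p = 0.775 with an estimated correlation, 2 of 3 pairs), with Hspa8 at 0.12 (SE 0.056) and Manf at 0.19 (SE 0.17). That call ended without WT_EE_1 (adjusted p = 0.0911) or CBP_EE_3 (0.206). Endothelial and pericyte genes had a median of 0.064 with 10 of 16 higher (adjusted p = 0.0380, adjusted p = 0.775 with an estimated correlation, 2 of 3 pairs), with Vtn, vitronectin, at 0.43 (SE 0.18). Without WT_EE_2, WT_EE_3, CBP_EE_1 or CBP_EE_2 the call ended (adjusted p = 0.052 to 0.187). Glucocorticoid-responsive genes had a median of 0.15 with 14 of 19 higher (adjusted p = 0.0429, adjusted p = 0.814 with an estimated correlation, 3 of 3 pairs), with Lcn2, lipocalin 2, at 1.13 (SE 0.56) and the kinase gene Pdk4 at -0.30 (SE 0.14). Lcn2 was at 0.52 (SE 0.53) without CBP_EE_3, with 0.44 in array set 1 and 2.50 in set 4, and Pdk4 at -0.17 without WT_EE_3. Leaving out WT_SC_4, WT_EE_3, CBP_EE_1, CBP_EE_2 or CBP_EE_3 ended it (adjusted p = 0.0517 to 0.572).

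Gene by gene in enrichment, 0 probe sets passed with limma, 1139 had an unadjusted p under 0.05, and array weights called 2474. Beside Pcdhb2, the smallest p belonged to Ptger4, a prostaglandin receptor (-0.26, SE 0.047), Tnnc1 (-0.29, SE 0.059), Myog (-0.31, SE 0.063) and Prrx1, a mesenchymal transcription factor (-0.27, SE 0.057), each with an adjusted p of 0.924 and lower in 3 of 3 pairs. Of the 100 probe sets with the smallest p, 79 were in the dimmer part of the array.

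Averaged over housings, protocadherin beta genes were higher on cbp+/- arrays, though not past the threshold as a list with an estimated correlation (adjusted p = 0.291). Pcdhb2 was 1.45-fold higher on cbp+/- arrays (log2 0.54, SE 0.092, adjusted p = 0.878, 8 of 8 pairs), and with quantile normalization and the array sets as a block it passed alone (adjusted p = 0.0360). Pcdhb10 differed by 0.30 (SE 0.076), Pcdhb6 by 0.28 (SE 0.075) and Pcdhb4 by 0.28 (SE 0.092), and these 4 passed adjusted over the list alone against 0 over all genes tested. Of 22 members 21 were higher (median 0.14, adjusted p = 1.4e-12, 7 of 8 pairs). Within the 4 array sets the list differed by 0.085, 0.17, 0.15 and 0.22.

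Immature granule neuron genes were lower on average, in list level in 8 of 8 pairs (median -0.058, 19 of 24 lower, adjusted p = 0.0390, adjusted p = 0.291 with an estimated correlation), with Sox11 at -0.30 (SE 0.10) and Sox4 at -0.19 (SE 0.098). By another measure, the median of the members' differences, they were lower in 7 of 8 pairs, and within array sets 1 to 4 it was -0.057, 0.0086, -0.058 and -0.085. Their adjusted p was 0.00857 with the set block, and leaving out WT_SC_1, WT_SC_2, WT_EE_2, WT_EE_3, CBP_SC_1, CBP_SC_4, CBP_SC_5 or CBP_EE_2 ended the call (adjusted p = 0.0612 to 0.302). Oligodendrocyte progenitor genes had a median of -0.090 with 10 of 11 lower (adjusted p = 0.0107, adjusted p = 0.291 with an estimated correlation, 6 of 8 pairs). Sox6 (-0.12, SE 0.034, 8 of 8 pairs) passed adjusted over the list alone, and Vcan, versican, was at -0.12 (SE 0.055). The call ended without WT_EE_2 (adjusted p = 0.082) or CBP_EE_2 (0.0849). Dentate granule genes had a median of -0.095 with 11 of 14 lower (adjusted p = 0.0468, adjusted p = 0.508 with an estimated correlation, 6 of 8 pairs), with Tdo2 at -0.13 (SE 0.055). Without WT_SC_1, WT_SC_4, WT_EE_2, WT_EE_3, CBP_SC_1, CBP_SC_2, CBP_SC_5, CBP_EE_2 or CBP_EE_3 that call ended (adjusted p = 0.0589 to 0.306).

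Endothelial genes had a median of 0.051 with 12 of 16 higher on average (adjusted p = 0.0217, adjusted p = 0.291 with an estimated correlation, 6 of 8 pairs), with Vtn at 0.34 (SE 0.12) and Vwf, von Willebrand factor, at 0.14 (SE 0.081). Leaving out WT_SC_5, WT_EE_2, WT_EE_3, CBP_SC_1 or CBP_EE_2 ended the call (adjusted p = 0.0634 to 0.159), as did quantile normalization (adjusted p = 0.0501). Chaperones had a median of 0.058 with 18 of 19 higher (adjusted p = 0.00569, adjusted p = 0.291 with an estimated correlation, 4 of 8 pairs), with Hspa5 at 0.088 (SE 0.067), and their call ended without CBP_EE_3 (adjusted p = 0.122) and with quantile normalization (adjusted p = 0.0626). Oxidative phosphorylation genes had a median of 0.072 with 25 of 28 higher (adjusted p = 0.00569, adjusted p = 0.725 with an estimated correlation), with Sdha at 0.14 (SE 0.077), but the list was higher in only 3 of 8 pairs. It ended without WT_EE_1 (adjusted p = 0.303), CBP_SC_5 (0.164) or CBP_EE_3 (0.548) and with quantile normalization (adjusted p = 0.0835).

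Gene by gene, 0 probe sets passed for the averaged genotype effect with limma and 852 had an unadjusted p under 0.05. The smallest p belonged to Pcdhb2, Bfsp2 (-0.19, SE 0.036, lower in 8 of 8 pairs), Nipsnap2 (0.21, SE 0.042, 7 of 8), Slc6a20a, a proline transporter (0.28, SE 0.058, 7 of 8), and Cdh4, the R-cadherin gene (-0.27, SE 0.060, lower in 8 of 8), with an adjusted p of 1.00 for all but Pcdhb2. With the set block 1 passed (Cdh4, adjusted p = 0.0430), with quantile normalization and the set block 5 passed, and array weights called 152. The genotype effects of the housings correlated across genes at Pearson's r of 0.21 and Spearman's rank correlation of 0.19, with 55.0% of probe sets of the same sign, and at r of -0.28 within array set 1.

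Whether the response to enrichment differed between genotypes was tested by the interaction. It gave 0 probe sets past the threshold with limma, 579 at an unadjusted p under 0.05 and 429 called with array weights. Among named genes the smallest p belonged to Myog (-0.36, SE 0.080), Cd79a, a B cell receptor subunit (-0.30, SE 0.066), Ptger4 (-0.25, SE 0.059), Rhox8 (-0.24, SE 0.059) and Lif, a cytokine of the interleukin 6 family (-0.41, SE 0.10), each with an adjusted p of 1.00. Of the 100 probe sets with the smallest p, 92 were in the dimmer part of the array and 8 above 0. Negative values mean a smaller or more negative housing effect in cbp+/-. The CREB-target list did not pass (median 0.047, adjusted p = 0.275, adjusted p = 0.680 with an estimated correlation), nor did the immediate early list pass (median -0.0049, adjusted p = 0.791, adjusted p = 0.916 with an estimated correlation) or the immature granule neuron list (median -0.037, adjusted p = 0.791).

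The interaction passed for 7 lists with the preset correlation and for 0 with an estimated correlation, with 0 members past the threshold over all genes tested or adjusted over the list alone. Excitatory synapse genes had a median interaction of 0.083 with 21 of 25 above 0 (adjusted p = 0.00664, adjusted p = 0.680 with an estimated correlation), with Camk2b at 0.23 (SE 0.21). Oligodendrocyte genes had 0.076 with 17 of 21 above 0 (adjusted p = 0.00326, adjusted p = 0.680 with an estimated correlation), with Cnp at 0.39 (SE 0.25), and astrocyte genes 0.082 with 10 of 16 (adjusted p = 0.00715, adjusted p = 0.680 with an estimated correlation), with Aldoc at 0.37 (SE 0.22) and Ppp1r3c at 0.30 (SE 0.15). Oxidative phosphorylation genes had 0.13 with 23 of 28 above 0 (adjusted p = 0.00326, adjusted p = 0.680 with an estimated correlation), with Atp5b at 0.22 (SE 0.17). Glucocorticoid-responsive genes had 0.15 with 15 of 19 (adjusted p = 0.0212, adjusted p = 0.726 with an estimated correlation), with Gpd1 at 0.32 (SE 0.20). Protocadherin beta genes had 0.094 with 17 of 22 (adjusted p = 0.00664, adjusted p = 0.726 with an estimated correlation), with Pcdhb2 at 0.38 (SE 0.18) and Pcdhb6 at 0.34 (SE 0.15). Choroid plexus genes had -0.23 with 20 of 21 below 0 (adjusted p = 0.00715, adjusted p = 0.726 with an estimated correlation), with Col8a1 at -0.33 (SE 0.16).

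Single arrays ended each of these interaction calls. For excitatory synapses these were WT_SC_3 (adjusted p = 0.051), WT_EE_3 (0.44) and CBP_SC_5 (0.138), for oligodendrocytes WT_SC_3 (0.0525) and WT_EE_3 (0.178), and for astrocytes WT_EE_3 (0.757) and CBP_EE_2 (0.0662). For oxidative phosphorylation they were WT_SC_5 (0.0705), WT_EE_1 (0.198) and CBP_EE_3 (0.552), and for the choroid plexus WT_EE_3 (0.0678) and CBP_SC_3 (0.329). For glucocorticoid-responsive genes they were WT_SC_3, WT_SC_5, WT_EE_3, CBP_SC_1, CBP_SC_2, CBP_SC_4 and CBP_EE_2 (0.0633 to 0.357), and for protocadherins WT_SC_1, WT_SC_2, WT_EE_1, CBP_SC_3, CBP_SC_4 and CBP_EE_3 (0.0556 to 0.237). With quantile normalization the choroid plexus (adjusted p = 0.0230) and protocadherin interactions (adjusted p = 0.0226) passed and the other 5 did not, and with dim probe sets left out 0 passed. Within array set 1 the oligodendrocyte interaction was -0.040. Several gene values rested on 1 array: without WT_EE_3 the interaction was 0.11 for Camk2b, 0.17 for Cnp, 0.12 for Aldoc and 0.14 for Gpd1, and without WT_SC_3 it was 0.13 for Atp5b.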

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

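Chosen only after the result was seen were the protocadherin values within array sets and tests against signal compression, shared probes and genotype. So were both tests of the choroid plexus genes and the splits of averaged effects that keep or part same-numbered pairs. The other splits of the arrays, the receptor test and the neighbours of the protocadherin cluster were set beforehand.

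On wild-type enrichment arrays dim probe sets were higher and bright ones lower. Olfactory and vomeronasal receptor genes, which the hippocampus hardly uses, were taken as a probe of this: their 1204 probe sets had a median change of 0.057 with 90.5% above 0 (two-sided exact permutation p = 0.0179, the smallest that 56 splits can give). Probe sets matched to them in brightness moved by 0.046, a difference of 0.011, which argues against changes of particular hippocampal genes as the whole cause. A narrower signal range on these arrays may be behind the shift of dim genes and partly that of excitatory synapse genes. In cbp+/- the receptor median was 0.0063.

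Protocadherin beta genes were higher on cbp+/- arrays, a call that is lost with an estimated correlation (adjusted p = 0.291 in the averaged effect). Array sets are balanced over genotypes, so the within-set differences (lowest 0.085 in set 1, where pair SC_1 was at -0.091) do not test them. Compression is argued against by the median of 0.16 after quantile normalization (adjusted p = 3.9e-13). Probes shared between near-identical copies stay open, since 20 of the 21 members other than Pcdhb2 were higher and 1 changed copy could move the rest. Strain variants around the cluster stay open too: the 40 nearest neighbours had a median of 0.024 (permutation p = 0.138). Genotype remains a hypothesis, with 7 of 8 pairs higher (two-sided exact sign-flip p = 0.0234, adjusted p = 0.242 over the lists).

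Choroid plexus genes were higher on cbp+/- arrays in standard cages. On CBP_SC_3, 19 of 21 members had their highest signal, and Ttr reached 6596 against a median of 260.6 elsewhere. Of the members 0 are in another list and 4 lie above the median signal of all genes on the other arrays. Without that array the adjusted p went from 8.0e-05 to 0.159, which is consistent with choroid plexus tissue in that pool. A genotype effect is argued against, as 2 of 5 pairs were higher.

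Other splits of the arrays into groups of the same sizes were refitted, and the number of probe sets at an unadjusted p under 0.05 compared. For the averaged housing effect chance cannot be excluded: 2 of 100 free splits were as large (real 4168, highest other 4338), but these part same-numbered pairs, and of 56 splits that keep the pairs together 11, the real one included, were as large (highest other 5450, joining the pairs SC_1, SC_5 and EE_3). Of those, the 12 within array sets are too few (highest other 3893). It cannot for the housing effect in wild type (3884, highest other 4269, 3 of 56 splits as large, the highest joining WT_SC_3 with WT_EE_1 and WT_EE_2), nor for that in cbp+/- (615, 3606, 26 of 56). It cannot for the genotype effect in standard cages (215, 4563, 88 of 100), the interaction (579, 4875, 51 of 100) or the averaged genotype effect (852, 6397, 58 of 100). For the genotype effect in enrichment the 10 splits are too few (1139, highest other 4294, 5 as large). In standard cages the highest split joined WT_SC_1, WT_SC_2, CBP_SC_1, CBP_SC_2 and CBP_SC_5, all but the last in array set 1, and with up to 1218 and 1893 adjusted calls the splits point to a structure of the arrays. Compared with splits that part as many same-numbered pairs, 3 of 9 were as large in standard cages (highest 661) and 15 of 100 in the averaged genotype effect (highest other 1997), while in enrichment there were 4 (highest other 1171). With the pairs as a block, 5 of 16 were as large in standard cages (957, highest other 2113), and in enrichment the 4 are too few (2838, highest other 2300).

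Single standard-cage arrays lay far from the others of their group in 18 of 254 tests, and chance alone gives about 1 in 20. In log2 signal, CBP_SC_3 stood apart for Col8a1 (6.21), Hsph1 (10.32), Kl (8.21) and Mbp (10.37), and CBP_SC_4 for Hspa5 (9.77), Pcdhb6 (6.30) and Penk (7.78). CBP_SC_5 stood apart for Lcn2 (7.90) and Sox6 (6.94), CBP_SC_2 for Lif (5.76), WT_SC_4 for Bdnf (6.62) and WT_SC_3 for Npas4 (6.77). In list level, CBP_SC_3 stood apart for immediate early (0.18), GABAergic (0.16) and choroid plexus genes (0.94), WT_SC_1 for choroid plexus genes (0.16), and WT_SC_5 (0.29) and CBP_SC_5 (0.39) for oxidative phosphorylation.

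The housing change differed between genotypes for 7 lists by the interaction with the preset correlation. Median changes in wild type and cbp+/- were -0.24 and -0.15 for excitatory synapse genes (adjusted p = 0.00664), -0.098 and -0.028 for oligodendrocytes (0.00326), -0.10 and 0.0016 for astrocytes (0.00715), 0.095 and -0.11 for choroid plexus (0.00715), -0.13 and 0.014 for glucocorticoid-responsive genes (0.0212), -0.12 and -0.029 for protocadherins (0.00664), and -0.027 and 0.11 for oxidative phosphorylation (0.00326). None holds with an estimated correlation (adjusted p = 0.680 to 0.726). Among the 7035 probe sets without a single gene name, 8 passed in the housing effect of wild type when all deposited probe sets were tested, with changes from -0.90 to 0.39.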

How the results depend on the processing

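The array-set block, quantile normalization with it, pairs within a housing and array set 1 alone were chosen after seeing the data, as were the tests of agreement with array weights and with a replicate block. Counts of probe sets past the threshold were 0 in all 7 comparisons and stayed 0 with quantile normalization, centring, dim probe sets left out and replicates 1 to 3, as they did in the 4 comparisons of 2 groups with only the groups compared. For the housing effect in wild type the count was 36 over all deposited probe sets (35 higher, 1 lower), 96 with trend and robust (all higher), 74 without moderation (73 higher, 1 lower), 15 with the array-set block (6 higher, 9 lower), 6513 in array set 1 only (3499 higher, 3014 lower) and 5254 with array weights (3712 higher, 1542 lower). Leaving out 1 array gave 0 to 19. For the averaged housing effect it was 5 with trend and robust, 11 without moderation, 15 with the array-set block, 9 with quantile normalization and that block, 5470 in set 1 only, 6167 with array weights, and 0 to 230 with 1 array left out, with 1 without WT_EE_2 and 230 without CBP_EE_3. Array weights called 1039 in cbp+/- housing, 2474 for genotype in enrichment, 429 for the interaction and 152 for the averaged genotype effect. The latter had 1 with the array-set block and 5 with quantile normalization added, namely Cdh4, Grp, Pcdhb2, Sorcs1 and Pcsk1, of which Grp, Sorcs1 and Pcsk1 are named after their values were seen. Weights ran from 0.261 for WT_EE_3 to 8.63 for CBP_EE_1. The cause was not tested.

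With the replicate number as a block the averaged housing effect had 326 calls (76 higher, 250 lower). The replicate block left the counts of the other 6 comparisons at 0. It gave 11 list calls in the averaged housing effect against 7, and ended 3 list calls: glucocorticoid-responsive genes in wild-type housing (adjusted p = 0.172), and dentate granule (0.0531) and CA3/CA2 genes (0.0627) in standard cages. With the pairs within a housing as a block, lists called in the averaged genotype effect were 11 against 7. It added CA1 (adjusted p = 0.00623) and excitatory synapse genes (0.00162) in standard cages, where the CA3/CA2 call ended (0.0862), dentate granule and progenitor genes in enrichment (both 0.0487, lower) and CA1 genes in the interaction (0.0362). It changed no other call in these 3 comparisons.

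List calls numbered 7, 8, 12, 5, 7, 7 and 7, for housing in wild type and cbp+/-, genotype in standard cages and enrichment, the interaction, and averaged housing and genotype. With an estimated correlation, with or without the array-set block, 1 passed in cbp+/- housing and 0 elsewhere. With fry 1 passed in each of the housing effects, 2 in their average and 0 elsewhere. The array-set block gave 4 in wild-type housing. In enrichment, genotype lists were 2 with dim probe sets left out and 8 with quantile normalization and set block. Interaction lists were 2 with quantile normalization, 0 with dim probe sets left out, 3 with quantile normalization and set block and 4 in set 1 only. Averaged genotype lists were 12 with replicates 1 to 3, 14 with quantile normalization and set block and 16 in set 1 only. With 1 array left out the calls ranged from 7 (without WT_SC_3) to 16 in standard cages, 2 (without CBP_EE_3) to 7 in enrichment, 3 (without WT_EE_3) to 9 for the interaction, 4 (without CBP_SC_1) to 8 for averaged housing and 3 (without WT_EE_2) to 9 for averaged genotype. Over 53 list results, 25 lost the call with quantile normalization, 29 without dim probe sets, 12 with the array-set block and 52 with an estimated correlation.

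Medians turned with quantile normalization and set block for acetylation (0.021) and astrocyte genes (0.020) in wild-type housing and oligodendrocytes in averaged housing (0.062). In set 1 only they turned for oligodendrocytes in wild-type housing (0.065), the interaction (-0.040) and averaged housing (0.083), and for glucocorticoid-responsive genes in wild-type housing (0.20, a call at adjusted p = 0.0383), while the choroid plexus test in standard cages turned at 0.0024. With 1 array left out the choroid plexus median ran from -0.18 to 0.029 in cbp+/- housing and from -0.014 to 0.16 in standard cages, in both turning without CBP_SC_3.

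Of 163 gene results, signs turned for Mag (0.079) and Clu (0.039) in wild-type housing with array weights. For Igf1 they turned in wild-type housing with quantile normalization (-0.0081), array weights (-0.045) and quantile normalization with set block (-0.055), in cbp+/- housing with the last (-0.032), and in averaged housing with array weights (-0.0035) and quantile normalization with set block (-0.044). Ttr in wild-type housing turned with replicates 1 to 3 (-0.62) and the replicate block (-0.64), and ran from -0.40 to 0.80 with 1 array left out. Ep300 turned in standard cages with array weights (-0.011) and replicates 1 to 3 (-0.018), and ran from -0.052 to 0.14 with 1 array left out. In enrichment it turned with array weights (0.022) and ran from -0.075 to 0.022. On average it turned with quantile normalization, with or without set block (-0.0076), and replicates 1 to 3 (-0.021), and ran from -0.038 to 0.059. Dcx in wild-type housing ran from -0.092 to 0.045 and Egr1 in cbp+/- housing from -0.061 to 0.27 with 1 array left out. The cause was not tested.

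The correlation of genotype effects between housings turned with array weights (-0.11) and in set 1 only (-0.28), and ran from -0.0037 (without CBP_SC_5) to 0.31 with 1 array left out. The odds ratio of genotype calls near Crebbp was 5.77 within 10 Mb, 2.13 within 20 Mb and 1.00 over its chromosome. Signal over background limits dim genes: RMA gives no detection call, and a narrower range of signals may shift dim genes as well as bright ones.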

Other observations

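The tests of Cirbp and Rbm3 and of the Crebbp probe set, and every value with the array sets as a block, were chosen only after the result was seen.

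Lists that passed in no comparison are given with their smallest adjusted p. Blood cell genes had a median of 0.087 in the averaged housing effect (8 genes, adjusted p = 0.0878), GABAergic interneuron genes -0.066 in wild-type housing (18 genes, adjusted p = 0.0814), CA1 genes -0.042 there (9 genes, adjusted p = 0.0909) and ribosomal protein genes -0.061 there (21 genes, adjusted p = 0.191). Proliferation genes had 0.035 in cbp+/- housing (29 genes, adjusted p = 0.0938), meningeal genes 0.022 there (17 genes, adjusted p = 0.197) and neurotrophins and growth factors -0.018 in averaged housing (18 genes, adjusted p = 0.333). Interferon and antigen presentation genes had 0.043 in standard cages between genotypes (20 genes, adjusted p = 0.0597), neural stem cell genes -0.040 (15 genes) and thalamic genes 0.025 (15 genes), both with adjusted p = 0.248. Microglial genes had 0.041 in the interaction (17 genes, adjusted p = 0.285). Striatal genes, called between genotypes in standard cages, also passed with fry in averaged housing (median 0.072, 11 of 13 higher, adjusted p = 0.0303), with Penk past the threshold adjusted over the list alone.

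With the array sets as a block, 15 probe sets passed in the averaged housing effect, against 0 without it. Apart from Npy, Cyp2d10 and Pcdhb18, their genes are named after their values were seen. Higher in enrichment were Apln, which encodes the peptide apelin (0.32), Serinc2 (0.34) and Htra4 (0.37). Lower were Rbm33 (-0.48), Srsf5, a splicing factor read by 2 probe sets (-0.33 and -0.35), Zranb1 (-0.26), Poc5 (-0.28), Xpot (-0.35), Tmem196 (-0.32) and Amy1 (-0.35). Between genotypes, paired differences over the 8 same-numbered pairs averaged -0.059 (SD 0.028) for immature granule neuron genes and -0.071 (SD 0.034) for striatal genes. Both list levels were lower in 8 of 8 pairs, with a two-sided exact sign-flip p of 0.00781, the smallest that 8 pairs can give, and an adjusted p of 0.121 over the lists.

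Cirbp, a cold-inducible RNA-binding protein gene, was lower in averaged housing with the set block (-0.52, adjusted p = 0.0469) and differed by -0.41 without it (adjusted p = 0.138). It was not among the 9 called with quantile normalization and that block. A hypothesis is that cold-inducible transcripts were lower as a group. Rbm3, the other cold-inducible member of the family, was at -0.38, -0.38 and -0.35 on its 3 probe sets with the set block, each with an adjusted p of 0.0948. The direction fits, but Rbm3 did not pass, and body temperature and time of day are not given in the sources used here.

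The mutant allele was carried on a mixed background, so variants linked to it might alter signals of neighbouring genes. No probe set passed the adjusted threshold, so an unadjusted p under 0.01 in the averaged genotype effect was used. Within 10 Mb of Crebbp on chromosome 16, 3 of 96 probe sets met it against 120 of 21589 elsewhere (odds ratio 5.77, two-sided Fisher exact p = 0.0174). Within 5 Mb these were 2 of 51 (odds ratio 7.26, exact p = 0.0340) and within 20 Mb the odds ratio was 2.13 (exact p = 0.174), and in standard cages alone 0 of 96 met it. The 3 genes, named after their values were seen, were Zfp263 (0.19, higher in 8 of 8 pairs), Ercc4 (0.16, 6 of 8) and Trap1 (0.17, 6 of 8). Linked variants stay a hypothesis, since 3 genes carry it.

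The Crebbp probe set was higher on cbp+/- arrays in 8 of 8 pairs (mean difference 0.12, SD 0.076, two-sided exact sign-flip p = 0.00781, the smallest that 8 pairs can give). The whole-transcript probe set may also read the transcript of the mutant allele. By itself that could account for a signal that is not lower, but not for a higher one. No value here separates the probes upstream and downstream of the mutation, so this stays open.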
